A study of Mus musculus with 4 samples.

How the data were processed

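Gene read counts were analysed for 4 RNA sequencing libraries of sorted mouse leukemia cells, 2 from the group labelled Scr and 2 from the group labelled miR-99 KD. Per the labels' protocols, cells were purified by flow sorting when the recipient mice died, RNA was extracted with Trizol LS, and libraries were made by SMARTer amplification, a template-switching method for small amounts of RNA. The series design gives 2 mice per group. The labels spell out neither Scr nor KD.

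The deposited values are raw read counts per Ensembl gene identifier, as the whole numbers and the differing library totals in the files show. Nothing in the files or labels says that the authors scaled these counts. Per the submitters' processing notes, the tools were STAR, Picard, HTSeq and DESeq2, with no versions, roles or order, and the genome build was mm9. The annotation release, the strand setting of the counting and the read layout are not given in the sources used here. Each file lists 45232 gene identifiers and 5 categories that name no gene. These categories stayed out of library sizes and tests. They held 49.7% of all entries in Scr 1, 43.7% in Scr 2, 43.7% in miR-99 KD 1 and 46.6% in miR-99 KD 2. The parts were alignments that were not unique (19.8%, 19.3%, 20.1% and 23.6%, in the same order), reads outside annotated genes (19.8%, 14.9%, 13.5% and 12.0%), reads not aligned (9.19%, 8.46%, 8.85% and 9.85%) and reads ambiguous between genes (0.984%, 1.16%, 1.21% and 1.10%). The category for low alignment quality held 0% in each library. Because alignments that were not unique were kept out of the gene counts, genes with near-identical copies are under-counted and their values are uncertain. Without a stated strand setting, reads of a gene and of an antisense neighbour cannot be told apart.

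Gene symbols were matched by identifier, and 44585 of the 45232 identifiers had one. Coordinates are those of GENCODE M21 on GRCm38, looked up by identifier. The files give no coordinates, and none were converted from mm9.

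Counts summed to 38458519 in Scr 1, 41870314 in Scr 2, 42674407 in miR-99 KD 1 and 42529111 in miR-99 KD 2. CPM values of genes are gene counts scaled to these totals, with no TMM factor. Values of log2 CPM, used for lists and correlations, were computed from the genes kept by the filter, with TMM factors. The same scaling was used to find genes in which both miR-99 KD libraries lay beyond both Scr libraries. A count of 0 allows up to 3 counts, which is 0.0780, 0.0716, 0.0703 and 0.0705 CPM in these libraries. Intervals of ratios are 95% intervals for counting error only, and reads amplified without molecular identifiers are not independent molecules.

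The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) of miR-99 KD against Scr, two-sided, with TMM factors, the default expression filter with its minimum count of 10, and Benjamini-Hochberg adjustment over the 15591 genes kept. The threshold was an adjusted p of 0.05. TMM factors were 1.07, 0.970, 0.969 and 0.993. The common biological coefficient of variation was 0.320, with 2 residual degrees of freedom and 2.41 prior degrees of freedom. Fold changes are log2 values of miR-99 KD over Scr with a standard error derived from the test statistic. The median over all genes tested was −0.01 with TMM factors, 0.03 with DESeq2 size factors and −0.03 with upper-quartile factors.

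Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over 26 lists. Their contents were written down before the data were examined, as were the design, the rule for named genes and the alternatives, apart from those named in the closing section as chosen later. The lists were granulocyte maturation, monocyte and macrophage, MLL-AF9 program, stem cell genes, described miR-99 family targets, S phase and DNA replication, G2 and mitosis, p53 targets, apoptosis regulators, ATF4 and amino acid stress, cholesterol synthesis, interferon response, inflammatory NF-kB targets, glycolysis and hypoxia, oxidative phosphorylation, ribosome biogenesis and Myc, ribosomal proteins, immediate-early and heat shock genes, MHC class II and dendritic cell, erythroid, megakaryocyte and platelet, mast cell basophil and eosinophil, T and NK cell, B cell, stroma and endothelium, and sort gate markers.

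Genes with a match to the miR-99 seed (ACCCGUA, positions 2 to 8) were found by searching the longest annotated 3' UTR of each gene in GENCODE M21 for TACGGGT, or for the match to positions 2 to 7 followed by A. They were tested with camera, beside 100 shuffled heptamers.

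Named genes followed a rule. With no gene past the threshold in a direction, it took the 5 genes with the smallest p in that direction. From each list past the list test it took the 2 members with the smallest p. It always took the microRNA genes and host transcripts of the miR-99 family, Mtor, Smarca5, Fgfr3, Hoxa9, Meis1, Kit, Ly6a, Cd34 and Fcgr3, and 1 further gene that is not reported here. Any other gene named was chosen after its values were seen.

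The edgeR test was tested on counts simulated from this comparison with 200 genes changed, and 15179 of the simulated genes passed the expression filter. It called 0 of 50 genes changed 2-fold, 27 of 49 changed 4-fold, 45 of 50 changed 16-fold and 50 of 50 changed 64-fold, with 13 false calls. DESeq2 called 10, 39, 47 and 50 of these, with 88 false calls. The simulated counts were independent between genes and had no library-wide disturbance such as that of Scr 1. On the data edgeR called 0 genes, although the log2 fold change of Vill was −10.00 (edgeR adjusted p 0.131). The simulation therefore overstates the power of the test here, and 0 calls do not show that large changes are absent. A simulated list of 28 independent genes raised 2-fold had a camera adjusted p of 4.17e-17 with the preset correlation and 0.970 with an estimated correlation. Neither form called any of 99 random lists. All these lists held independent genes, so false calls on lists of correlated genes were not simulated.

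Alternatives were DESeq2 (version 1.42.0), limma-voom, DESeq2 size factors, upper-quartile factors, no filter or a filter of 50 counts in 2 libraries, the 10 most abundant genes left out, the replicate number as a block, an adjusted p of 0.1, an added 2-fold minimum, and each library left out in turn. For lists they were an estimated correlation, fry, ranks and a prior count of 0.5. Replicate libraries were not duplicates, since the chi-square per degree of freedom between their counts was 136 in Scr and 142 in miR-99 KD. No sequencing batch or date is given in the sources used here, and an exact permutation test of 2 against 2 libraries cannot go below 0.333, so library-level values are given without a test.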

Results

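Gene expression was measured by RNA sequencing in leukemic granulocyte-macrophage progenitors (L-GMPs), sorted from mice that were secondary recipients of leukemia driven by MLL-AF9. MLL-AF9 is a fusion oncoprotein of acute myeloid leukemia, and L-GMPs are the leukemic cells that resemble normal granulocyte-macrophage progenitors. The labels call the sorted cells leukemic stem cells. Cells came from 2 mice in the group labelled Scr and 2 mice in the group labelled miR-99 KD, 1 library per mouse. The comparison asks how reducing miR-99, a microRNA family, changes the transcriptome of these cells at the time of death. Whether the 4 recipients received cells of 1 primary leukemia is not given in the sources used here.

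Gene counts per library were 38458519 and 41870314 in Scr and 42674407 and 42529111 in miR-99 KD. Scr 1 stood apart from the rest. It had at least 1 count in 28573 genes, against 22310 in Scr 2, 21372 in miR-99 KD 1 and 24038 in miR-99 KD 2. Olfactory receptor (Olfr) genes, which blood cells do not normally use, held 51.9 CPM in Scr 1 (95% Poisson interval 49.6 to 54.2), 5.52 CPM in Scr 2, 4.78 CPM in miR-99 KD 1 and 15.0 CPM in miR-99 KD 2. Across genes, which are not independent replicates, log2 CPM correlated at r 0.968 between the Scr libraries, 0.977 between the miR-99 KD libraries and 0.978 between Scr 2 and miR-99 KD 1, so these last 2 were closer to each other than to the other library of their group. The other between-group values ran from 0.957 to 0.958. Mitochondrially encoded genes held 0.650% and 0.637% of counts in Scr and 0.853% and 1.16% in miR-99 KD.

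The microRNA genes themselves could not be followed in these libraries. Mir99a, Mir99b and Mir100 had 0 counts in each of the 4 libraries, where 0 counts allow up to 0.0780 CPM in the least deep one. Mature microRNAs are too short for this kind of library, so these counts do not check the reduction of miR-99. The host transcript Mir99ahg had 59 counts in Scr 1, 3 in Scr 2, 1 in miR-99 KD 1 and 2 in miR-99 KD 2.

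Genes of the sorting gate were expressed in both groups, with the exception of Ly6a. Kit, the stem cell factor receptor c-Kit, had 438 ± 21 CPM (SD, n = 2) in Scr and 265 ± 46.3 CPM in miR-99 KD. Cd34 had 320 ± 53.2 and 339 ± 8.24 CPM, and Fcgr3, an Fc gamma receptor of the gate, had 403 ± 47.0 and 447 ± 49.0 CPM. The label lists Sca-1 among the positive markers, and its gene Ly6a had 4 and 8 counts in Scr and 5 and 4 counts in miR-99 KD. The log2 fold changes were −0.67 ± 0.19 (SE) for Kit, 0.15 ± 0.15 for Cd34 and 0.21 ± 0.15 for Fcgr3, with edgeR adjusted p of 0.580, 0.794 and 0.741. The list of sort gate markers, with 4 of 5 members measured, had a median log2 fold change of 0.18, a mean of −0.0044 and a camera adjusted p of 0.711. In it, 0 members passed adjusted over the list alone, 1 was lower at an unadjusted p under 0.05 in edgeR, and DESeq2 called 0.

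The single genes with the smallest p differed widely in level between the groups, and all but Epha7 were under 1 CPM in the group where they were lower. Vill, which encodes a villin-like protein, had 128 ± 17.2 CPM in Scr and 0.117 ± 0.0993 CPM in miR-99 KD. Eps8l1, a relative of the actin regulator Eps8, had 8.27 ± 1.25 CPM in Scr and 1 count in each miR-99 KD library, a ratio of 351 with a 95% counting interval of 96.7 to 2901. Krtcap3 (22.6 ± 3.91 against 0.610 ± 0.0981 CPM), the antisense gene Gm16299 (9.63 ± 0.337 against 0.246 ± 0.0492 CPM) and Cacna1b, a subunit of N-type calcium channels (15.3 ± 1.42 against 0.692 ± 0.148 CPM), were also at higher levels in Scr. In the other direction, the ephrin receptor gene Epha7 had 10.4 ± 1.75 CPM in Scr and 188 ± 33.6 CPM in miR-99 KD, and the calpain gene Capn11 had 0.0629 ± 0.0214 and 8.13 ± 0.335 CPM. The noncoding transcript Gm43305 had 0.537 ± 0.0498 and 32.3 ± 11.9 CPM, and the X-linked gene Xlr4c had 0.138 ± 0.0259 and 4.13 ± 0.674 CPM. The noncoding 1700030C10Rik (ENSMUSG00000099759) had 0 counts in both Scr libraries and 18.8 ± 3.73 CPM in miR-99 KD, at least 252-fold higher against a floor of 3 counts per library.

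None of these 10 genes passed the threshold over all genes. Their edgeR adjusted p lay between 0.131 and 0.152, with log2 fold changes from −4.41 ± 0.33 (Cacna1b) to −10.00 ± 0.59 (Vill) and from 4.22 ± 0.28 (Epha7) to 7.01 ± 0.37 (Capn11) for those with counts in both groups. Of 15591 genes tested, edgeR called 0, with 414 higher and 816 lower in miR-99 KD at an unadjusted p under 0.05. DESeq2 called 261 genes, 113 higher and 148 lower, the 10 above among them, and limma-voom called 0. In the simulation DESeq2 made 88 false calls and edgeR 13, so an adjusted p of DESeq2 can be too low here. Without Scr 1, which leaves 1 Scr library assumed to vary like the other group, edgeR called 294 genes, 158 higher and 136 lower, and DESeq2, in a fit chosen after seeing the data, called 139. Of the 294, 166 were among the 261 of DESeq2, but the 2 fits share 3 libraries, so this overlap is not independent evidence. Both miR-99 KD libraries lay beyond both Scr libraries in 6901 genes, 44.3% of those tested, where chance gives 33.3% for a single gene. Genes vary together between libraries, so the share over all genes can differ from 33.3% without a group effect. The shares of the other splits of the libraries are not given here.

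On GRCm38 the genes lower in miR-99 KD lie at chromosome 9, 119052778 to 119071525 (Vill), chromosome 7, 4460674 to 4480487 (Eps8l1), chromosome 5, 31251691 to 31253202 (Krtcap3), chromosome 19, 53819354 to 53825128 (Gm16299) and chromosome 2, 24603887 to 24763152 (Cacna1b). Those higher lie at chromosome 4, 28813131 to 28967499 (Epha7), chromosome 17, 45630204 to 45659325 (Capn11), chromosome 14, 54292443 to 54297456 (Gm43305), chromosome X, 73233688 to 73243130 (Xlr4c) and chromosome 12, 20804381 to 20815779 (1700030C10Rik). Xlr4c has close paralogs, and exons of 1700030C10Rik overlap those of Gm28503 and of a second gene with the same symbol, so their counts are uncertain. Exons of Eps8l1 overlap the antisense gene Gm15494.

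**Figure D1:**
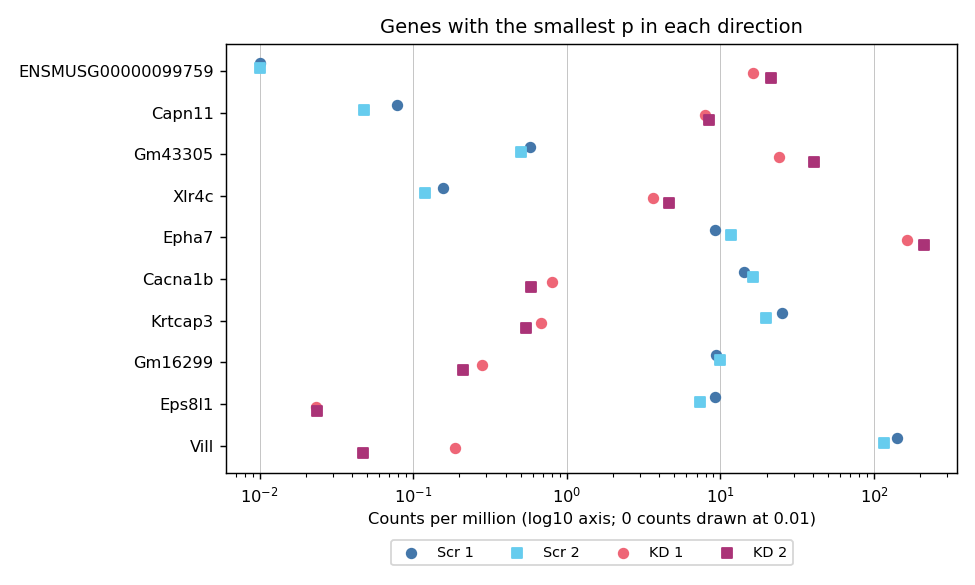
Expression of the 5 genes with the smallest edgeR p in each direction, in CPM on a log axis, with 1 point per library (Scr 1 blue circle, Scr 2 cyan square, miR-99 KD 1 red circle, miR-99 KD 2 purple square). A count of 0, as for 1700030C10Rik (drawn under its identifier) in both Scr libraries, is drawn at 0.01 CPM, and the 2 groups do not overlap in any of the 10 genes.

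Genes of granulocyte maturation rose as a group in miR-99 KD, in a call that rests on the preset correlation (camera adjusted p 8.30e-10, adjusted p = 0.872 with an estimated correlation). Of 28 measured members, 25 had a positive and 3 a negative log2 fold change, with a median of 1.21. Mpo, the myeloperoxidase of primary granules, had 608 ± 149 CPM in Scr and 3514 ± 1698 CPM in miR-99 KD, and Ltf, the lactoferrin of secondary granules, had 3.39 ± 2.23 and 98.6 ± 65.0 CPM. Other abundant members, chosen after their values were seen, were the elastase gene Elane (2305 ± 739 and 5281 ± 2141 CPM), the secondary granule gene Ngp (294 ± 208 and 3090 ± 2448 CPM) and the calprotectin gene S100a8 (77.7 ± 69.7 and 870 ± 611 CPM). The 3 members with a negative fold change were Ctsg (−0.09 ± 0.26), Padi4 (−0.37) and Csf3r (−0.04). The whole list took 1.25% and 0.781% of counts in the Scr libraries and 1.80% and 3.74% in the miR-99 KD libraries.

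The granulocyte list had a mean log2 CPM of 6.48 and 5.84 in Scr and 7.36 and 8.05 in miR-99 KD. No member passed over all genes in edgeR, where Mpo (log2 fold change 2.59 ± 0.40) and Ltf (4.94 ± 0.77) both had an adjusted p of 0.421. Adjusted over the list alone, 2 members passed, Mpo and Ltf, and 15 were higher at an unadjusted p under 0.05. DESeq2 called 9 members higher. Scr 1, the library with the high Olfr counts, was also the Scr library with the higher list mean. Without it, which leaves 1 Scr library, the list's median log2 fold change was 1.63. Exons of Mpo overlap the antisense gene Gm11505. Both miR-99 KD libraries also had the higher mitochondrial share of counts, 0.853% and 1.16% against 0.650% and 0.637%.

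**Figure D2:**
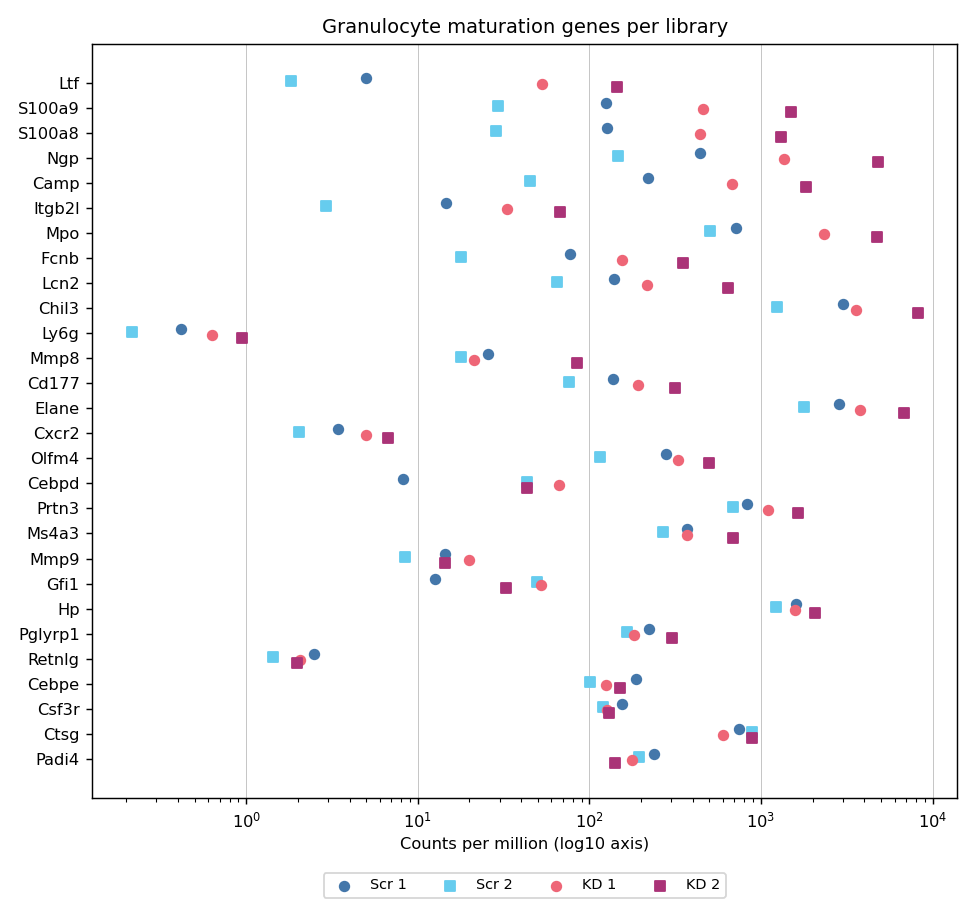
Expression of granulocyte maturation genes in CPM on a log axis, with 1 point per library in the same colours and symbols. Mpo lies at 713 and 503 CPM in Scr and at 2313 and 4714 CPM in miR-99 KD, while Csf3r lies between 120 and 155 CPM in all 4 libraries.

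Ribosomal protein genes, respiratory chain genes and cell cycle genes had slightly higher values in miR-99 KD as lists, in calls that rest on the preset correlation. All 36 ribosomal protein genes had a positive log2 fold change, with a median of 0.37 and a camera adjusted p of 8.51e-09 (adjusted p = 0.872 with an estimated correlation). Rps3 had 639 ± 40.9 CPM in Scr and 856 ± 138 CPM in miR-99 KD, and Rpl7 had 196 ± 12.3 and 283 ± 58.0 CPM. Of 30 oxidative phosphorylation genes 27 were positive, with a median of 0.25 (camera adjusted p 0.00205, adjusted p = 0.909 with an estimated correlation), among them the cytochrome c oxidase genes Cox5a (97.1 ± 7.48 and 150 ± 37.0 CPM) and Cox8a (130 ± 18.7 and 174 ± 41.8 CPM). The mean log2 CPM of oxidative phosphorylation genes was 6.85 and 6.72 in Scr and 6.85 and 7.19 in miR-99 KD, so miR-99 KD 1 was not above Scr 1. Of 24 genes of G2 and mitosis 21 were positive, with a median of 0.27 (camera adjusted p 7.30e-04, adjusted p = 0.872 with an estimated correlation). They included the mitotic kinesin Kif11 (277 ± 10.1 and 373 ± 44.3 CPM) and the ubiquitin-conjugating enzyme Ube2c (125 ± 12.9 and 181 ± 50.6 CPM). Of 28 genes of S phase and DNA replication 18 were positive, with a median of 0.17 (camera adjusted p 0.0342, adjusted p = 0.872 with an estimated correlation), among them the polymerase subunit Pola1 (109 ± 0.292 and 140 ± 8.94 CPM) and cyclin E2, Ccne2 (79.7 ± 7.31 and 107 ± 11.0 CPM).

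No member of the 4 lists passed edgeR over all genes, and 0 passed adjusted over the list alone. At an unadjusted p under 0.05, edgeR had 2 ribosomal protein genes, 1 oxidative phosphorylation gene, 1 gene of G2 and mitosis and 1 gene of S phase higher and 0 lower, and DESeq2 called 0. The call for S phase ended without Scr 1 (camera adjusted p 0.241) or miR-99 KD 1 (0.0622), the call for G2 and mitosis without Scr 1 (0.0515), and that for oxidative phosphorylation without Scr 2 (0.118) or miR-99 KD 2 (0.204). Exons of Ube2c and Ccne2 overlap those of the genes Tnnc2 and Ints8 on the opposite strand, and those of Rps3 and Cox5a overlap the noncoding Snord15b and Gm26631.

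Erythroid genes fell as a group, from low levels. Of 16 measured members 12 had a negative log2 fold change, with a median of −1.26 and a camera adjusted p of 1.25e-04 (adjusted p = 0.872 with an estimated correlation). Car1, a carbonic anhydrase of red cells, had 0.522 ± 0.0391 CPM in Scr and 0.0939 ± 0.0334 CPM in miR-99 KD, and the erythroid membrane gene Ermap had 0.846 ± 0.425 and 0.0822 ± 0.0168 CPM. The alpha globin gene Hba-a1, with 712 and 804 counts in Scr and 462 and 1256 in miR-99 KD, and the beta globin gene Hbb-bs, with 1608, 1976, 1217 and 3008 counts, did not share this direction. Their log2 fold changes were 0.14 ± 0.51 and 0.20 ± 0.47. All list members together, globins included, took 0.0102% and 0.0124% of counts in Scr and 0.00572% and 0.0137% in miR-99 KD, so this share was highest in miR-99 KD 2. In edgeR 0 members passed over all genes or adjusted over the list alone, and 6 were lower at an unadjusted p under 0.05. DESeq2 called 1 lower, the anion exchanger Slc4a1 (226, 730, 40 and 85 counts, adjusted p 0.00464), and edgeR without Scr 1 called 5. The list call ended without miR-99 KD 1 (camera adjusted p 0.283) and with a stricter filter on low counts (0.0825).

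Lists of other blood and marrow cells did not pass the list test. The monocyte and macrophage list had a median log2 fold change of 0.16 over 26 members (camera adjusted p 0.897). Adjusted over the list alone it held 1 gene with higher values, F13a1 (a coagulation factor subunit of monocytes, 0.90 ± 0.16), and 2 with lower values, the proteoglycan gene Vcan (−2.07 ± 0.27) and the integrin gene Itgax (−2.42 ± 0.36). The stroma and endothelium list had a median of −0.74 over 9 members (camera adjusted p 0.222), and the adhesion gene Vcam1 (476 and 430 CPM in Scr, 201 and 137 CPM in miR-99 KD) and Sparc (2.78, 2.05, 0.539 and 0.846 CPM) passed in it adjusted over the list alone. That list passed camera without Scr 2, a fit in which Scr 1, with the high Olfr counts, is the only Scr library. The list's mean log2 CPM was 3.16 in Scr 1, 2.17 in Scr 2, 2.23 in miR-99 KD 1 and 1.77 in miR-99 KD 2. The B cell list had a median of 0.14, a mean of −0.11 and a camera adjusted p of 0.897, with the recombinase gene Rag2 (−1.40 ± 0.21) passing adjusted over the list alone. The T and NK cell list had a median of 0.23, a mean of −0.16 and an adjusted p of 0.711, with the NK receptor gene Klrb1c (−2.41 ± 0.38) passing in it alone. The megakaryocyte and platelet list (median −0.48, camera adjusted p 0.201), the mast cell, basophil and eosinophil list (0.19, 0.711) and the MHC class II and dendritic cell list (median −0.17, mean 0.06, 0.890) held no such gene. At an unadjusted p under 0.05, edgeR had 1 lower in each of the former 2 lists and 1 higher in the latter, and DESeq2 called 0.

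Genes of the MLL-AF9 program did not pass the list test. Over 25 members the median log2 fold change was −0.09, with 8 positive and 17 negative members and a camera adjusted p of 0.579. Hoxa9, a homeobox gene that MLL fusions activate, had 326 ± 35.5 CPM in Scr and 167 ± 2.68 CPM in miR-99 KD, and its cofactor Meis1 had 339 ± 28.6 and 213 ± 24.7 CPM. Their log2 fold changes of −0.92 ± 0.19 and −0.61 ± 0.16 had edgeR adjusted p of 0.466 and 0.580. Tcf4, a basic helix-loop-helix factor, was the single member that passed adjusted over the list alone, with 3.02 ± 1.13 CPM in Scr and 29.3 ± 13.2 CPM in miR-99 KD (log2 fold change 3.34 ± 0.46, edgeR adjusted p over all genes 0.356, DESeq2 adjusted p 1.06e-08). In this list 2 genes were higher and 4 lower at an unadjusted p under 0.05 in edgeR, DESeq2 called 1 higher and 1 lower, and edgeR without Scr 1 called 2 higher and 3 lower. The stem cell list had a median of −0.08 and a mean of −0.06 over 15 members, a camera direction of up and an adjusted p of 0.897, and no member passed adjusted over the list alone. In it, 2 genes were higher and 3 lower at an unadjusted p under 0.05 in edgeR, and DESeq2 called 1 lower.

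Genes described as miR-99 family targets did not pass the list test and went both ways. Over 19 measured members the median log2 fold change was 0.13, the mean −0.17 and the camera adjusted p 0.667, and no member passed adjusted over the list alone. At an unadjusted p under 0.05 edgeR had 1 higher and 1 lower, and DESeq2 called 1 lower. The growth kinase gene Mtor had 72.1 ± 1.0 and 58.8 ± 18.2 CPM (−0.24 ± 0.28, adjusted p 0.818), and Smarca5, a chromatin remodeler, had 44.7 ± 32.2 and 56.3 ± 14.3 CPM (0.35 ± 0.63, adjusted p 0.876). Smarca5 changed sign without Scr 1 (−0.21) and Mtor without miR-99 KD 2 (0.10). The growth factor receptor gene Fgfr3 had 22 and 15 counts in Scr and 0 in both miR-99 KD libraries, at least 6.61-fold lower, with an adjusted p of 0.466 in edgeR, 0.0374 in DESeq2 and 0.0468 in edgeR without Scr 1.

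Transcripts with a miR-99 seed match did not pass the test against other genes. Of 12384 tested genes with an annotated 3' UTR, 327 had a match. Their median log2 fold change was −0.01, and that of the other genes with a 3' UTR was also −0.01. As a single test, not adjusted over other sets, the set had a camera p of 0.867 (camera p 0.928 with an estimated correlation). Over 100 shuffled heptamers the median ran from −0.11 to 0.02, and the miR-99 median stood at percentile 90 of them. Of these shuffled sets, 88 had a camera p as low as that of the miR-99 set. The 37 genes with the match to positions 2 to 8 followed by A had a median of −0.05 (camera p 0.533).

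The remaining lists did not pass the list test. Of stress and survival lists, p53 targets had a median log2 fold change of −0.23 (camera adjusted p 0.201), apoptosis regulators −0.12 (0.348), ATF4 and amino acid stress genes −0.21 (0.115), and immediate-early and heat shock genes −0.14 (0.519). Bcl2a1d, an antiapoptotic Bcl2 relative with near-identical paralogs (−2.76 ± 0.32), and the lipoprotein receptor gene Vldlr (−2.89 ± 0.35) passed adjusted over the apoptosis list alone and the ATF4 list alone. Without Scr 1 the ATF4 list passed camera, with an adjusted p of 0.0398. Cholesterol synthesis genes had a median of 0.13 (camera adjusted p 0.294), glycolysis and hypoxia genes 0.18 (0.10), ribosome biogenesis and Myc genes −0.09 (0.711), interferon response genes −0.15 (0.711) and inflammatory NF-kB targets −0.10 (0.348). Without miR-99 KD 2 the cholesterol list passed, with an adjusted p of 1.88e-05. In these 5 lists, and in the p53 and immediate-early lists, 0 members passed adjusted over the list alone. The unadjusted edgeR counts under 0.05 were 5 lower and 2 higher for immediate-early genes, 3 lower for p53 targets, 2 lower and 2 higher for interferon genes, 2 lower for NF-kB targets, 1 lower for ribosome biogenesis, 1 higher for glycolysis and 0 for cholesterol synthesis, and DESeq2 called 2 immediate-early genes lower, 1 interferon gene in each direction and 0 in the other 5 lists.

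**Figure D3:**
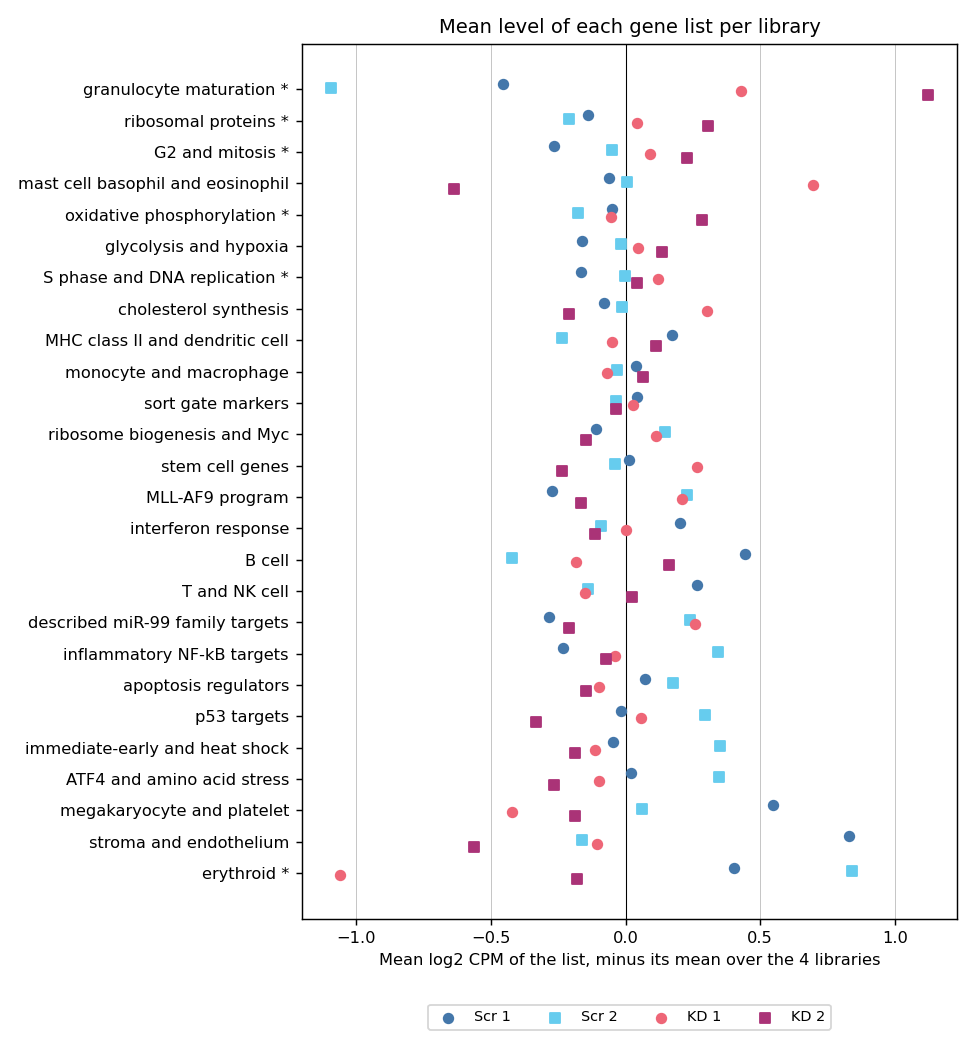
Mean log2 CPM of each of the 26 gene lists in each library, minus the list's mean over the 4 libraries, in the same colours and symbols, with an asterisk where the camera adjusted p was under 0.05 with the preset correlation. Granulocyte maturation lies at 6.48 and 5.84 log2 CPM in Scr and at 7.36 and 8.05 in miR-99 KD before centring, and oxidative phosphorylation, with an asterisk, has 6.85 in both Scr 1 and miR-99 KD 1.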

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

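The depth test for Scr 1 in this part was chosen after the library totals had been seen, and the test on olfactory receptor genes before those genes had been counted.

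Alignments that were not unique, which enter no gene count, took 20.1% of all entries in miR-99 KD 1 and 23.6% in miR-99 KD 2, above the 19.8% and 19.3% of the Scr libraries. The difference was not tested, and the reads behind it were not used here.

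Scr 1 had counts in 28573 genes, more than the 21372 to 24038 of the other 3 libraries, and 19.8% of its entries lay outside annotated genes, against 12.0% to 14.9%. Deeper sequencing is excluded by the totals, since Scr 1 had 0.919 times the gene counts of the least deep of the others, and although its 76531414 entries of all kinds exceeded those of Scr 2 (74432088) and miR-99 KD 1 (75784900), miR-99 KD 2 had 79651164 and fewer genes detected. Reads that do not come from expressed genes, such as genomic DNA carried through amplification, may account for it, because olfactory receptor genes held 3.47 times the CPM of the next highest library, and 603 of them had a count in Scr 1 against 89 to 295 elsewhere. The source of such reads was not tested. No biological explanation was tested, since both Scr libraries carry 1 label and Scr 2 does not share the pattern.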

How the results depend on the processing

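The crossed pairing, edgeR with robust estimation, edgeR's newer quasi-likelihood form and DESeq2 without Scr 1 were chosen after seeing the data.

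The count of genes changed depended on the tool, the scaling, the filter and Scr 1. Against 0 genes in the edgeR test (414 higher and 816 lower at an unadjusted p under 0.05), DESeq2 called 261, edgeR with upper-quartile factors 23 (10 higher, 13 lower), without a filter 9 (5 and 4), and in its newer form 1 (lower). The count was also 0 with limma-voom, DESeq2 size factors, the stricter filter, the 10 most abundant genes left out, robust estimation, an adjusted p of 0.1 and an added 2-fold minimum. Leaving out 1 library gave between 0 and 294 genes. The 294 came without Scr 1, where DESeq2 called 139, and the other 3 gave 0 in edgeR, with 1222 higher and 1048 lower (without Scr 2), 1110 and 1570 (without miR-99 KD 1) and 247 and 423 (without miR-99 KD 2) at an unadjusted p under 0.05. In these fits the lone library of a group is assumed to vary like the other group. The cause of these shifts was not tested.

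The replicate numbers gave no sign of a pairing: deviations of same-numbered libraries from their group means correlated at −0.428 across genes. With 2 libraries per group, the value for differently numbered libraries is the mirror image, 0.428. Library-wide differences such as those of Scr 1 could set this sign, so a pairing by number is not excluded. With the number as a replicate block edgeR called 0 genes (219 higher and 431 lower at an unadjusted p under 0.05), 5 lists passed, S phase had a camera adjusted p of 0.0809, B cell genes turned upward at 0.968, and the seed-match set turned upward at 0.951. A block that pairs Scr 1 with miR-99 KD 2 and Scr 2 with miR-99 KD 1 gave 28 genes.

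Of 26 lists, 6 passed camera with the preset correlation, 0 with an estimated correlation and 0 with fry, 6 with size factors, ranks or the smaller prior count, 8 without a filter, 4 with the stricter filter, and 4 to 6 with 1 library left out. With an estimated correlation the adjusted p was 0.909 for oxidative phosphorylation and 0.872 for the other 5 lists. With fry it was 0.394 for granulocyte, S phase, G2 and mitosis and ribosomal protein genes, 0.595 for oxidative phosphorylation and 0.413 for erythroid genes. The ribosomal protein and granulocyte lists passed in every other setting tried. In simulation the estimated correlation also missed a list of independent genes raised 2-fold, at an adjusted p of 0.970. That was a camera p of 0.00970 before adjustment with 99 random lists. Correlations estimated from the data were 0.464 for granulocyte, 0.799 for ribosomal protein, 0.691 for oxidative phosphorylation and 0.496 for erythroid genes. They were 0.257 for G2 and mitosis and 0.0109 for S phase, against the preset 0.01. The simulation, with independent genes, does not show how either form behaves on correlated lists. The stricter filter ended S phase (0.0786) and erythroid genes (0.0825), and no filter added cholesterol synthesis (0.0290) and glycolysis (0.0139).

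Leave-one-out adjusted p ranged from 0.00144 to 0.241 for S phase, 1.52e-04 to 0.0515 for G2 and mitosis, 1.69e-06 to 0.204 for oxidative phosphorylation and 8.14e-09 to 0.283 for erythroid genes. It ranged from 0.0398 to 0.890 for ATF4 genes, 1.88e-05 to 0.690 for cholesterol synthesis, which also changed direction, and 0.00790 to 0.756 for stroma. Lists that never passed but changed direction ranged from 0.194 to 0.942 (MLL-AF9 program), 0.579 to 0.942 (stem cell), 0.131 to 0.884 (miR-99 targets), 0.429 to 0.903 (interferon), 0.305 to 0.690 (NF-kB), 0.689 to 0.753 (ribosome biogenesis), 0.142 to 0.903 (immediate-early), 0.312 to 0.805 (MHC class II), 0.315 to 0.993 (megakaryocyte), 0.184 to 0.923 (mast cell), 0.661 to 0.839 (T and NK) and 0.159 to 0.837 (B cell).

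Direction of lists that did not pass also turned with fry for monocyte (0.595), stem cell and miR-99 target genes (both 0.921). It turned without a filter for MLL-AF9 program and B cell (both 0.932), stem cell (0.303), interferon (0.735), ribosome biogenesis (0.637) and T and NK genes (0.759). It turned with the stricter filter for monocyte (0.917), stem cell (0.422), MHC class II (0.331) and B cell genes (0.484), and with ranks for MHC class II (0.906), T and NK and B cell genes (both 0.984). The seed-match set ranged from 0.423 to 0.671 with 1 library left out and changed direction. Of named genes, the log2 fold change of Mtor ranged from −0.55 to 0.10, of Smarca5 from −0.21 to 1.54 and of Ctsg from −0.35 to 0.20. The cause was not tested. Counts of 1 to 8 per library leave Ly6a and Mir99ahg in 3 libraries without a usable fold change.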

Other observations

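The tests of mature neutrophils, of Scr 1 as the sole source and of a swap were chosen after the results they bear on had been seen in part, the genes in this part were chosen after their values were seen, and the other tests were fixed before their values were computed, although the on-off pattern itself was noticed in the DESeq2 results.

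Several regulators were called by DESeq2 on 4 libraries and by edgeR without Scr 1, fits that share 3 libraries, though not by edgeR on 4 libraries. Adjusted p of DESeq2 can be too low here, since it made 88 false calls in the simulation. Cdkn2c, an inhibitor of the cell cycle kinases Cdk4 and Cdk6, had 15.5 ± 4.52 CPM (SD, n = 2) in Scr and 149 ± 64.5 CPM in miR-99 KD (edgeR adjusted p 0.335, DESeq2 adjusted p 6.43e-11). The receptor tyrosine kinase gene Met had 3.33 and 9.48 CPM in Scr and 35.5 and 41.0 CPM in miR-99 KD. Hnf4a, a nuclear receptor best known from liver, had 47.3 ± 8.30 and 1.5 ± 0.926 CPM, and the transcription factor gene Wt1 had 4.46 ± 0.647 and 0.117 ± 0.0335 CPM. The AP-1 gene Junb had 86.1 and 86.0 CPM in Scr and 35.4 and 26.0 CPM in miR-99 KD, and the zinc finger gene Egr1 had 14.5, 49.7, 3.66 and 0.823 CPM. Hoxa3 had 12.1, 15.0, 4.78 and 4.73 CPM.

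Genes known from germ cells were not tested as a list, and those given here are picked from the calls and went both ways. Stag3, a cohesin subunit of meiosis, had 81.0 and 70.9 CPM in Scr and 13.1 and 6.30 CPM in miR-99 KD. The germ cell RNA helicase gene Ddx4 had 18.0, 24.8, 5.06 and 3.65 CPM, and Tdrkh, which acts in piRNA processing, had 23.3, 15.3, 3.73 and 5.27 CPM. Their DESeq2 adjusted p were 9.85e-08, 7.18e-06 and 1.19e-04. Mcmdc2 (5.28, 5.16, 0.680 and 0.682 CPM) and Piwil2 (1.98, 1.89, 0.351 and 0.353 CPM) were also lower in miR-99 KD, while Tdrd9, another gene of piRNA processing (0.130, 0.0720, 4.64 and 0.282 CPM), and Dmrtb1 (9.98, 8.69, 42.3 and 212 CPM) were higher. The X-linked paralogs Xlr4a (0.116 ± 0.130 and 18.7 ± 3.55 CPM) and Xlr4b (3 counts in Scr in all, a ratio of 125 with a counting interval of 42.6 to 611) had higher values in miR-99 KD, as Xlr4c did, and counts of such close paralogs are uncertain.

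The higher granulocyte values in miR-99 KD were set against 3 technical explanations. Scr 1 alone does not account for them. Its mean log2 CPM of the list, 6.48, was nearer to miR-99 KD than the 5.84 of Scr 2. Leaving Scr 1 out could therefore only be expected to widen the difference, so the list's median log2 fold change of 1.63 without it adds no separate test. That median was 1.08 without Scr 2, 1.57 without miR-99 KD 1 and 0.913 without miR-99 KD 2. Dilution of Scr by erythroid cells is excluded by an erythroid share of at most 0.0137% of counts. Mature neutrophils that passed a gate for c-Kit and CD34, which should remove them, could add such transcripts, and cannot be told apart from a change in the leukemic cells: the median of 6 early genes minus that of 12 late genes was −0.495 (0.84 and 1.33, exact permutation p 0.390 over genes, two-sided). All 18 belong to the granulocyte list and progenitors express several of them; S100a8 (127, 28.4, 438 and 1303 CPM) and S100a9 (125, 29.4, 457 and 1494 CPM) were the most abundant late genes in miR-99 KD but not in Scr, where Padi4 (238 and 193 CPM) led, while Retnlg (2.50, 1.43, 2.06 and 1.98 CPM) and Csf3r (155, 120, 126 and 130 CPM) were level. A difference in the leukemic cells themselves, by miR-99 KD or between individual leukemias, stays open and was not tested.

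Genes on in 1 group and off in the other, with at least 5 CPM in both libraries of 1 pair and 16-fold above both others, numbered 16 in the labelled split, 10 on in Scr and 6 in miR-99 KD. The other 2 splits of the 4 libraries gave 0 each, so the labelled split was the 1 split of 3 with as many. These counts speak against a swap of a Scr with a miR-99 KD library. Correlations across genes hardly separated the splits. The mean r of log2 CPM within pairs was 0.972 in the labelled split. It was 0.968 with Scr 1 paired with miR-99 KD 2, and 0.957 with Scr 1 paired with miR-99 KD 1. Scr 1 correlated with the miR-99 KD libraries at 0.957 and 0.958, below the 0.968 of the Scr pair. Scr 2 and miR-99 KD 1 stood higher, at 0.978. With 3 splits no share can go under 0.05, and the bound set beforehand, under 0.5 times as many in each other split, was wrong for that reason. Release of direct targets cannot be judged, since 0% of the 4 genes on in miR-99 KD with a 3' UTR had a seed match (95% interval up to 60.2%) against 2.64% of other tested genes (Fisher's exact p = 1). Switches of this kind may instead reflect separate starting leukemias. The labels name 0 primary leukemias, so it is not known whether the leukemia of origin differed between the groups, and this could not be tested.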
